A study of Homo sapiens with 3 samples.

How the data were processed

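The samples were primary human keratinocytes, transduced with a retrovirus carrying Flag-tagged DLX3, transduced with the empty vector, or not transduced, with RNA collected 24 hours later. Each of these 3 groups had 1 array here, grouped by the submitters' source labels. The labels speak of biological replicates, but whether an array holds RNA of 1 culture or a pool was not given in the sources used here. Per the labels' protocols, total RNA was extracted with Trizol and prepared and labelled with biotin by the standard Affymetrix procedure. The deposited table holds signal intensity on a linear scale, computed by the authors with MAS5, per the submitters' processing notes; its version, target scaling and detection calls were not given in the sources used here. The values themselves show a common scale: the mean after trimming 2% at each end was 499.838, 499.839 and 499.829 on the 3 arrays. The table has 22277 probe sets, of which 62 are controls, and no further scaling was applied to it.

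Probe sets were named through the platform's annotation, with symbols updated through the Entrez identifier to the RefSeq gene table of assembly GRCh38.p14, used for names only; no genome build was given in the sources used here and no coordinates are reported. Of 22215 non-control probe sets, 19064 had 1 gene symbol, 1043 had several and 2108 were unnamed here; 19052 of the first took their symbol from the RefSeq table. Probe sets with several symbols or none were left out of gene counts, and so were genes that could tell a donor's sex. This gave 11939 named genes. Each gene was represented by its probe set of highest mean log2 signal. A common floor was set at 162.8, the highest of the arrays' 50th percentiles over non-control probe sets; lower signals were raised to it, and a gene was kept where its probe set reached the floor on at least 1 array. This left 7549 genes, 5709 of them at or above the floor on all 3 arrays. A fold with a side at the floor is a bound.

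With 1 array per group no test, p-value or error was computed. A gene counted as higher or lower on the DLX3-Flag array when it was at least 2-fold apart from both controls in the same direction, and the same count with each control array set apart served as the benchmark. For each pair of arrays, genes at least 2-fold apart were counted. In all, 28 gene lists were described by their median log2 difference and by its percentile among 10000 random lists of the same size, drawn from 20 bins of mean signal; lists with under 3 measured genes got no median. Further probe sets were compared with the same floor, a choice made after their differences without a floor had been seen; their share of equal direction has a Wilson 95% interval, which covers counting only. The named genes were the 12 higher and 12 lower with the largest smaller-of-2 difference from both controls among genes measured on all 3 arrays, up to 4 per direction with a side at the floor, taken by signal, the 3 highest and 3 lowest genes of each control array, the DLX family, and from each list the members 2-fold apart from both controls or else up to 2 with the highest signal. The floor, the fold, the probe set rule, the lists, the named-gene rule and the alternatives below, unless said otherwise, were fixed before the data were examined.

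The alternatives were median scaling and quantile normalization of the arrays, floors at the 30th and 70th percentiles, no floor, a pseudocount equal to the 50th percentile in place of the floor, the mean over a gene's probe sets, the probe set with the middle difference, leaving out probe sets with the suffixes _x_at and _s_at, thresholds of 1.5-fold and 3-fold, the mean of a list, and random lists without matching. Chosen after seeing the data were scaling by the 9 hybridisation spike-in probe sets, scaling by the median of probe sets at or above the floor on all arrays, counts against each control array alone, the EGF family list without feedback inhibitors, the floor for further probe sets, and 5 gene lists, of NRF2 targets, metallothioneins, gap junction connexins, lysosomal genes and an ERK output set. Each alternative scaling or floor set the genes kept anew, so a list could hold other genes under it. The counting was tested on simulated data of 7549 genes with a noise of 0.332 log2 units. Of genes set 2-fold apart 36% were recovered, of genes set 4-fold apart 95%, and 0.463% of unchanged genes were counted. The noise came from the closest pair, DLX3-Flag and empty vector, whose differences had a spread of 0.47, against 0.62 for the control arrays. Changed genes lay more than 2 log2 units above the floor and no shift between arrays was simulated, so these rates may be too favourable for these arrays. For lists of 20 genes, 7% of lists without a shift lay outside the central 95% of random lists, and a list shifted by 0.5 on the log2 scale lay at the 99.7th. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.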

Results

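The study asked what DLX3, a homeobox transcription factor of the differentiating epidermis, does to gene expression when it is delivered to primary human keratinocytes, the main cells of the epidermis, grown from skin. Messenger RNA was profiled with Affymetrix arrays 24 hours after transduction. There were 3 arrays: 1 of cells given a retrovirus carrying Flag-tagged DLX3, 1 of cells given the empty vector and 1 of untransduced cells. Each group had 1 array, of RNA from 1 culture or a pool (not given in the sources used here), so no difference below has a replicate check, and the number of arrays limits the precision of every value. Folds and log2 differences describe these arrays. Signals below a common floor of 162.8 were set to the floor, and a fold with a side at the floor is given as "at least". The median signal was 162.8 on the DLX3-Flag array, 148 on the empty-vector array and 141 on the untransduced array. On them 6837, 6594 and 6486 genes respectively were at or above the floor.

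The delivered gene could not be checked here, because no probe set was named for DLX3 or DLX1. Among its relatives, DLX2 had signals of 266 on the DLX3-Flag array, 406 on the empty-vector array and 1234 on the untransduced array. It was 4.64-fold and 3.04-fold lower on the DLX3-Flag and empty-vector arrays than on the untransduced one. DLX4 was above the floor only on the DLX3-Flag array, at 207, and this was at least 1.27-fold higher than either control. Its other probe set was below the floor on all 3 arrays, at 73.8, 18 and 101.4 on the DLX3-Flag, empty-vector and untransduced arrays. Probe sets of DLX5 and DLX6 were below the floor on all 3 arrays.

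On the DLX3-Flag array 3 of 9 measured heat shock genes and 4 of 23 unfolded protein response genes were at least 2-fold higher than on both controls. In the unfolded protein response list 2 others were at least 2-fold lower than both. Of 14 measured genes of the basal layer 5 were at least 2-fold lower, and so were 3 of 20 cytokine and NF-kB response genes, IL1A and IL1B among them. SQSTM1, which encodes the autophagy receptor p62, had a signal of 15406 with DLX3, 3765 with empty vector and 2469 without transduction, 4.09-fold and 6.24-fold higher. DUSP6, a phosphatase that is transcribed in response to ERK signalling and dampens it, had a signal of 191, 12.6-fold and 16.1-fold lower than in the empty-vector and untransduced cells. In all, 139 genes were at least 2-fold higher and 186 at least 2-fold lower on the DLX3-Flag array than on both controls, out of 7549 genes kept. The same count with the empty-vector array set apart gave 51 higher and 33 lower, and with the untransduced array set apart 320 higher and 455 lower. The higher and lower split depended on the scaling between arrays: it was 67 to 271 when the arrays were scaled to a common median and 21 to 603 when they were scaled to their spiked-in hybridisation controls, but 123 to 205 with quantile normalization and 127 to 193 with scaling to the median of bright probe sets. Spike-in scaling moved the median of all genes by -0.44 on the log2 scale for DLX3-Flag minus empty vector and by -0.31 for DLX3-Flag minus untransduced. Median scaling moved the latter by -0.13, so that differences are relative to these choices. All 186 lower genes remained with median, spike-in and bright-probe scaling and 184 with quantile normalization. Median, spike-in and bright-probe scaling each lowered the DLX3-Flag array against both controls. Apart from floor effects, genes already 2-fold lower had to remain so, and their retention does not test scaling. Of the 139 higher genes 67 remained with median, 21 with spike-in, 117 with quantile and 127 with bright-probe scaling. The benchmark moved too: with the empty-vector array set apart, 234 genes were higher with spike-in scaling, more than the 21 of the DLX3-Flag array. It was 57 with median, 50 with quantile and 47 with bright-probe scaling. As deposited, the empty-vector array lay between the others. Its log2 differences had a spread of 0.47 from DLX3-Flag and 0.62 from untransduced, against 0.76 for DLX3-Flag from untransduced. An array in between has few genes apart from both others, so its counts are no background rate. Of the genes named in these comparisons, CLU, DDX52, JUN, RBL2, SC5D and SDF2L1 were under 2-fold from a control with both median and spike-in scaling and CALR, HSP90AA1, HSPA2, PI3 and SPRR2C with spike-in scaling.

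Among the 12 genes highest on the DLX3-Flag array, HSP90B1, the chaperone of the endoplasmic reticulum, was 3.80-fold higher than with empty vector and 8.49-fold higher than in untransduced cells. The cytosolic chaperone genes DNAJA1 (3.33-fold and 13.7-fold) and HSPH1 (3.20-fold and 5.53-fold) were higher too. The ribosomal protein genes RPLP2 (6.80-fold and 7.45-fold) and RPL27A (3.18-fold and 3.22-fold) and the histone genes H3-3A (5.49-fold and 10.6-fold) and H2BC12 (3.43-fold and 6.61-fold) stood with them. Ribosomal protein genes did not stand apart as a group. RPLP2 was the only 1 of 15 measured genes of that reference list 2-fold above both controls, and the list median was 0.13 against empty vector. The tight junction gene CLDN4 was 3.13-fold and 3.19-fold higher, the zinc finger gene ZBTB40 3.21-fold and 3.27-fold, and SOS1, which encodes a RAS exchange factor, 3.10-fold and 3.50-fold. The galactosyltransferase gene B4GALT1 was 8.03-fold and 3.55-fold higher by its brightest probe set. Of its other 3 probe sets none was higher, with log2 differences from empty vector of 0.00, -0.67 and -0.59. Of genes at the floor on the untransduced array, HSPA2, a chaperone gene, was 2.26-fold higher than with empty vector and at least 9.29-fold higher than untransduced. CLU, which encodes a secreted chaperone, was 2.03-fold and at least 8.03-fold higher, DDX52, an RNA helicase gene, 2.08-fold and at least 9.44-fold, and ZNF165 4.15-fold and at least 6.11-fold. A further probe set was measured for 54 of the 139 higher genes. Of these 76 further probe sets, 64 (84.2%, Wilson 95% interval 74.4 to 90.7) were higher than both controls and 29 at least 2-fold. That of ZBTB40 was not, at log2 differences of 0.53 and at least 0.67, nor was 1 of DDX52, at 0.23 and at least 0.87.

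Among the 12 genes lowest on the DLX3-Flag array, DDIT4, an inhibitor of mTORC1, had a signal of 1618 against 13551 and 20185, 8.38-fold and 12.5-fold lower. PHLDA1 was 6.21-fold and 17.3-fold lower, and MYC, a transcription factor of growth and proliferation, 5.45-fold and 11.7-fold. The interleukin-1 genes IL1A (6.40-fold and 5.72-fold) and IL1B (5.74-fold and 9.49-fold) were lower than in both controls. AQP3, the epidermal water and glycerol channel, was 5.58-fold and 22.0-fold lower, and SNAI2, a transcription factor of epithelial migration, 4.94-fold and 19.8-fold. ID1, a target of BMP signalling, was 4.68-fold and 16.5-fold lower and the lysosomal protease gene CTSC 4.74-fold and 5.71-fold. G0S2, which encodes an inhibitor of lipolysis, was 6.72-fold and 4.38-fold lower, and FJX1 4.40-fold and 5.10-fold. At the floor on the DLX3-Flag array, the thrombomodulin gene THBD was at least 3.63-fold and at least 10.5-fold lower. EREG, which encodes the EGF receptor ligand epiregulin, was at least 6.2-fold and at least 8.04-fold lower, the neuregulin gene NRG1 at least 3.61-fold and at least 9.14-fold, and AMIGO2 at least 6.48-fold and at least 6.49-fold. For the lower genes, 79 of 101 further probe sets, measured for 71 of the 186, were lower than both controls and 40 at least 2-fold. Those of AQP3 were under 2-fold from empty vector, at -0.28 and -0.72, as was that of THBD, at -0.73, and 1 of PHLDA1, at -0.75.

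**Figure D1:**
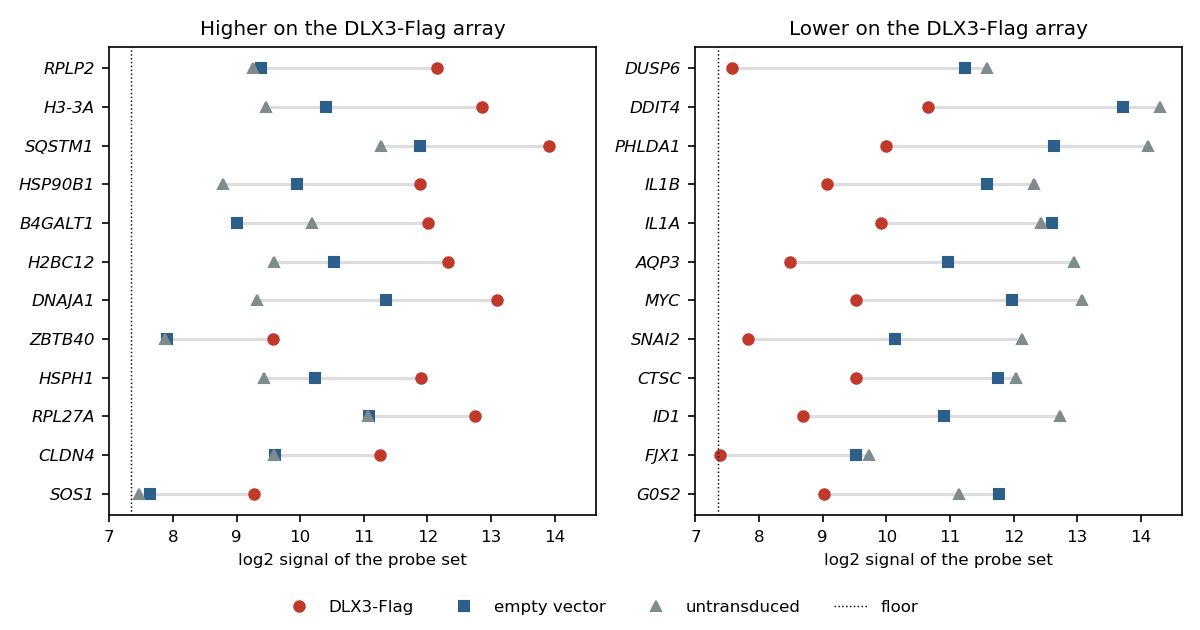
Log2 signal of the 12 genes highest (left) and the 12 lowest (right) on the DLX3-Flag array relative to both controls, among genes measured on all 3 arrays; each point is 1 array, with DLX3-Flag as circles, empty vector as squares and untransduced as triangles, and the dotted line is the floor at a signal of 162.8. The genes are ordered by the smaller of their 2 differences from the controls, and each circle lies at least 2-fold away from both other points.

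Gene lists fixed beforehand placed these genes in groups, and each list's median was set against 10000 random lists of equal size and similar signal. A percentile among them describes these arrays only, and is not a p-value, since genes of a list vary together. The list of the basal layer and its hemidesmosomes was lower with DLX3 by its median. Over 14 measured genes the median was -0.56 on the log2 scale against empty vector (percentile 0.01) and -1.32 against untransduced cells (percentile 0). Of them, 5 were at least 2-fold lower than both: the integrin genes ITGA6 (2.91-fold and 2.04-fold) and ITGA3 (3.13-fold and 8.17-fold), the P-cadherin gene CDH3 (2.72-fold and 6.31-fold), the caveolin gene CAV1 (4.44-fold and 2.66-fold) and the anchoring fibril gene COL7A1 (at least 2.09-fold and at least 3.79-fold). A further COL7A1 probe set was under 2-fold from either control, at log2 differences of -0.21 and -0.27. Of the 14 genes 13 were below empty vector, but not all by much. The keratin genes KRT5 (0.15 and -0.14) and KRT14 (-0.08 and -0.24) lay near both controls. ITGB4 and LAMB3 each differed from empty vector by -0.05, and were already lower on the empty-vector array than on the untransduced one (-1.27 and -1.49). In the spinous, early differentiation list the Notch pathway genes JAG1 (2.94-fold and 6.92-fold), JAG2 (2.48-fold and 4.04-fold) and HES1 (2.80-fold and 4.27-fold) were the 3 of 18 measured genes lower than both controls; further probe sets of JAG2 and HES1 differed from empty vector by 0.18 and -0.999. That list had medians of -0.21 against empty vector (percentile 3.53) and -1.12 against untransduced cells (percentile 0).

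Genes of the granular layer and cornified envelope were higher with DLX3 than with empty vector: the median of 25 measured genes was 0.66 (percentile 100), and 0.16 with spike-in scaling. Against untransduced cells it was 0.08 (percentile 68.3), a value that was negative with 3 other scalings, the lowest being -0.17 with spike-in scaling. The 3 members higher than both controls were the corneodesmosin gene CDSN (at least 3.58-fold from either), the elafin gene PI3 (2.47-fold and 4.54-fold) and SPRR2C (2.46-fold and at least 4.63-fold). Genes linked to DLX3 in earlier work had a median of 0.36 against empty vector (percentile 99.8), which was 0.00 with spike-in scaling, and -0.15 against untransduced cells (percentile 11.9). None of the 12 measured was 2-fold apart from both, and the brightest, the calprotectin genes S100A9 (16225, 10223 and 7760.5 with DLX3, empty vector and no transduction) and S100A8 (12294, 6644 and 11568), did not stand apart together: S100A8 against untransduced cells was at -0.12 with median and -0.33 with spike-in scaling.

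Protein folding genes were among the higher genes. All 9 measured heat shock genes were above both controls, with medians of 0.98 (percentile 100) and 1.24 (percentile 100); with spike-in scaling the medians were 0.44 and 0.82. HSP90AA1, the inducible cytosolic HSP90, was 2.41-fold and 13.0-fold higher, and was 1 of 3 members 2-fold above both, with DNAJA1 and HSPH1. The unfolded protein and integrated stress response list (23 genes) had a median of 0.64 against empty vector (percentile 100; 0.10 with spike-in scaling) and 0.10 against untransduced cells (percentile 70.9), the latter -0.32 with spike-in and -0.10 with median scaling. Its members were split: the endoplasmic reticulum chaperone genes HSP90B1, DNAJC3 (3.38-fold and at least 3.43-fold), CALR (2.23-fold and 2.69-fold) and SDF2L1 (2.13-fold and 2.46-fold) were higher than both controls, while DDIT4 and the glutathione-degrading CHAC1 (2.71-fold and 3.04-fold) were lower. In the cholesterol synthesis list (17 genes) SC5D was 2.17-fold and 7.03-fold higher; the medians were 0.21 (percentile 95.1; -0.33 with spike-in scaling) and 0.58 (percentile 98.4). RBL2, of the retinoblastoma family, was 2.29-fold and 2.27-fold higher, but its other probe set, at or near the floor on all arrays, was not higher (-0.056 and 0.00).

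Beside these groups, the DLX3-Flag array differed in its control probe sets. The 28S ribosomal RNA 5′ probe set had a signal of 3087 on it, 14.5-fold and 13.8-fold above the empty-vector and untransduced arrays, and the 18S ribosomal RNA 3′ probe set had 952.8, at least 5.85-fold above either. Hybridisation spike-ins were 1.45-fold and 1.34-fold higher by the geometric mean of 9 probe sets. The ratio of 3′ to 5′ signal was at most 1.19 times that of a control array for ACTB and GAPDH. Both the higher and the lower gene groups above were read from this array.

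**Figure D2:**
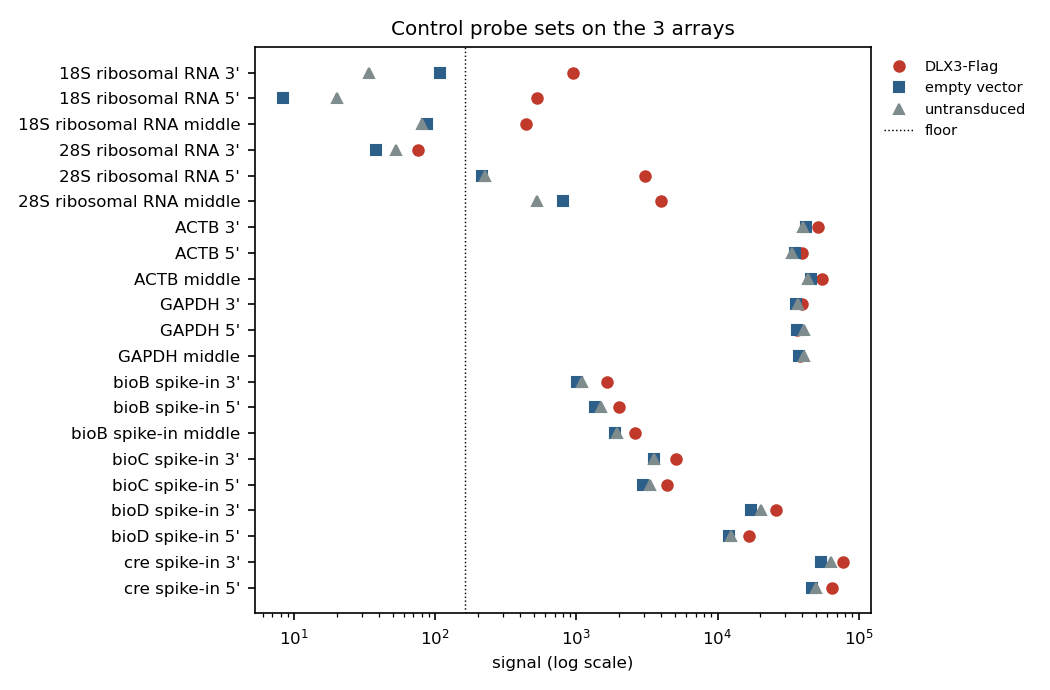
Signal (log scale) of the ribosomal RNA, ACTB, GAPDH and hybridisation spike-in control probe sets on the DLX3-Flag (circles), empty-vector (squares) and untransduced (triangles) arrays, 1 point per array; the dotted line is the floor. The 18S sets and the 5′ and middle 28S sets lie above both controls on the DLX3-Flag array, and the spike-ins lie above by 1.45-fold and 1.34-fold on average.

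Signalling and inflammatory genes were among the lower genes. The EGF family list of receptors, ligands and their feedback inhibitors had medians of -0.79 (percentile 0.01) and -1.19 (percentile 0.01) over 10 measured genes, of which EGFR (2.16-fold and 3.89-fold), EREG, NRG1 and the feedback gene DUSP6 were lower than both controls. Without the feedback inhibitors DUSP6, SPRY2 and SPRY4, left out after the values were seen, the medians over 7 genes were -0.50 (percentile 1.58) and -1.25 (percentile 0.05). Of 4 further EGFR probe sets 3 were lower, by -0.83 to -1.11 against empty vector, and 1, below the floor on both controls, was higher by at least 0.52. All 3 further NRG1 probe sets were at the floor with empty vector. With DLX3 1 was higher, by at least 0.19, and 2 were at the floor, with bounds of -0.79 and -1.02 against untransduced cells. Of 19 immediate early genes, which respond first to growth factors, FOS (at least 2.17-fold and at least 5.15-fold), EGR1 (2.43-fold and 5.95-fold), IER3 (3.29-fold and 3.95-fold), KLF6 (2.54-fold and 3.57-fold) and MYC were lower than both controls, and JUN was 2.06-fold and 2.48-fold higher. Of 2 further KLF6 probe sets 1 was not 2-fold apart (-0.22 and 0.00). The medians of the list were -0.12 (percentile 20.4) and -1.35 (percentile 0). Targets of TGF-beta and BMP had medians of -0.50 (percentile 0.11) and -0.73 (percentile 0.2) over 13 genes, with ID1, ID3 (at least 3.36-fold and at least 2.89-fold) and THBS1 (2.57-fold and 5.84-fold) lower than both. Cytokine and NF-kB response genes (20 measured) had medians of -0.32 (percentile 0.41) and 0.15 (percentile 70, and -0.09 with spike-in scaling), with IL1A, IL1B and the prostaglandin synthase gene PTGS2 (2.81-fold and 3.35-fold) lower.

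Single genes of other lists were also lower than both controls. They were, in the order of empty vector and untransduced cells, the protease gene PLAU (5.38-fold and 3.66-fold), VEGFA (3.99-fold and 12.3-fold), the WNT antagonist gene DKK1 (3.55-fold and 3.90-fold) and its relative DKK3 (3.19-fold and 5.70-fold). The polo-like kinase genes PLK2 (2.97-fold and 3.14-fold) and PLK3 (2.02-fold and 3.93-fold) were lower too. A further PLK3 probe set was at the floor with both DLX3 and empty vector (0.00). For JUN, VEGFA, DKK3 and THBS1 at least 1 further probe set was 2-fold apart from both controls and at least 1 was not. Type I interferon response genes (21 measured) had a median of -0.46 against empty vector (percentile 0.06) and -0.19 against untransduced cells (percentile 6.99); none was 2-fold apart from both, and ISG15 had signals of 776, 1160.5 and 888. Medians of the remaining lists against empty vector and untransduced cells were 0.10 and -0.10 for hyperproliferation genes (percentiles 82.0 and 20.4), 0.01 and -0.44 for p53 targets (54.5 and 3.08). They were -0.08 and -0.01 for cell cycle inhibitors and D cyclins (16.6 and 37.9). They were 0.00 and -0.36 for the STAT3 pathway (43.7 and 3.73), -0.22 and 0.07 for hypoxia genes (8.75 and 62.6) and -0.06 and -0.22 for WNT and hair follicle genes (11.0 and 4.14). Against empty vector, the medians of hyperproliferation genes and p53 targets turned to -0.17 and -0.49 with spike-in scaling, and that of p53 targets to -0.13 with median and -0.05 with quantile scaling. Against untransduced cells that of hypoxia genes turned to -0.14 with median and -0.35 with spike-in scaling.

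Reference lists lay near 0: 0.13 and -0.09 for ribosomal proteins (percentiles 93.0 and 41.4; -0.06 with quantile and -0.40 with spike-in scaling against empty vector) and -0.21 and -0.07 for housekeeping genes (8.47 and 36.2), whose brightest members were ACTB (70288, 54962 and 51418 on the DLX3-Flag, empty-vector and untransduced arrays) and GAPDH (52148, 43814 and 44966), both lower than with empty vector under spike-in scaling (ACTB -0.18, GAPDH -0.29). Markers of other skin cells were few. Of the fibroblast list 7 genes were measured, with medians of 0.08 and 0.16 (percentiles 77.4 and 91.5), and VIM was 2.77-fold and 2.01-fold lower. With spike-in scaling the medians were -0.79 and -0.52, but over the genes kept after that scaling, which were not the same 7. They therefore do not show a shift of these 7 genes. The melanocyte genes MITF and TYR had signals of 389 and 172 with DLX3, 219 and 145 with empty vector and 257 and 30.9 without transduction, TYR being below the floor on both controls. Of endothelial genes 0 were above the floor. The leukocyte list (5 genes, with LCP1 and CORO1A brightest) had medians of -0.10 and 0.00 (percentiles 6.12 and 36.8). Merkel cell and sweat gland markers, with KRT18 and KRT19 brightest, had medians of -0.14 and 0.57 over 4 genes (percentiles 32.0 and 94.9).

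**Figure D3:**
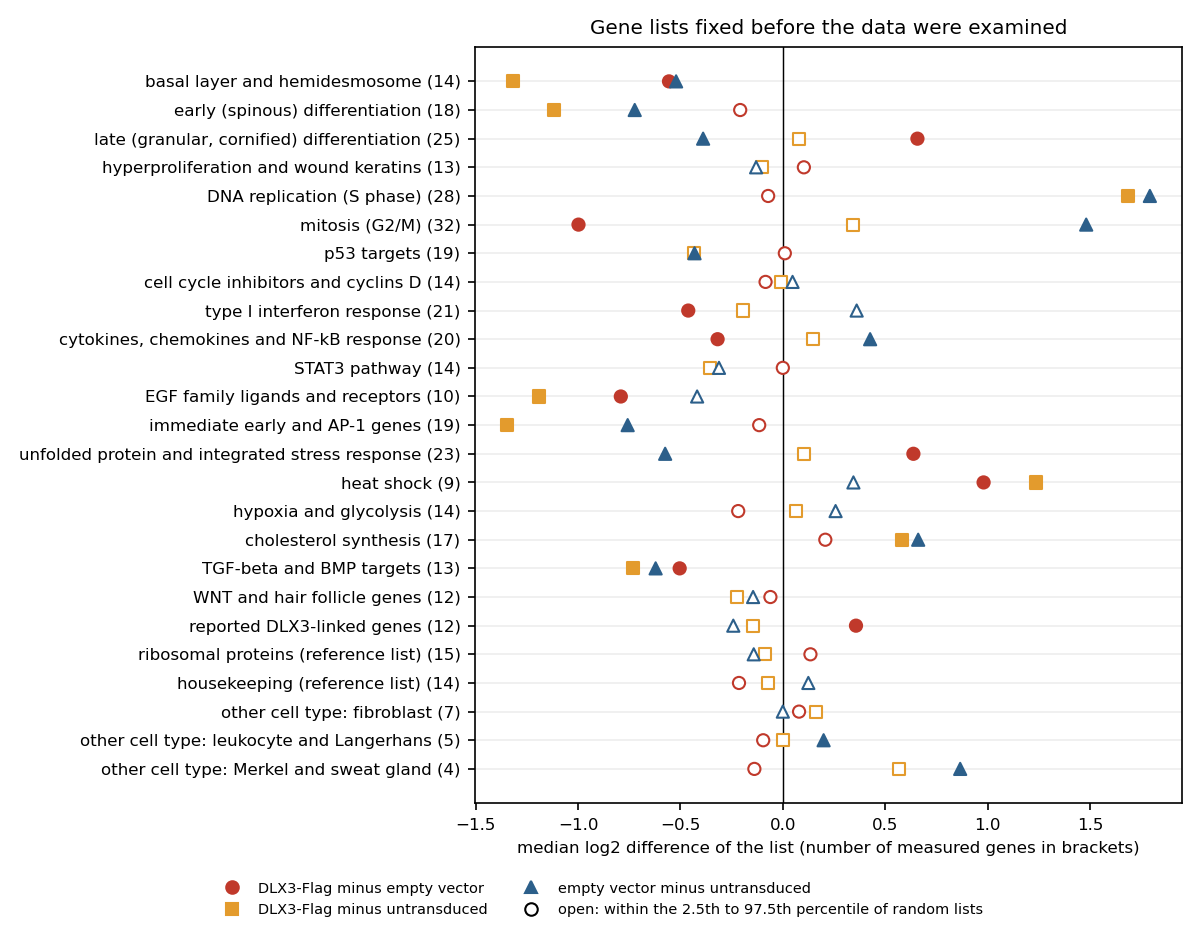
Median log2 difference of each gene list for DLX3-Flag minus empty vector (circles), DLX3-Flag minus untransduced (squares) and empty vector minus untransduced (triangles); the bracketed number is how many genes of the list were measured. Filled points lie outside the central 95% of 10000 random lists and open points within; heat shock genes are at 0.98 and 1.24 and DNA replication genes at 1.69 and 1.79 against untransduced cells.

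The comparison with empty vector alone, which holds the vector constant, set mitotic genes apart. All 32 measured mitosis genes were lower with DLX3, 16 of them at least 2-fold, with a median of -0.998 (percentile 0). The anaphase activator gene CDC20 had signals of 907 with DLX3, 3054 with empty vector and 1907 without transduction, and was the 1 member lower than both, by 3.37-fold and 2.10-fold. The mitotic kinesin KIF20A (4.06-fold) and topoisomerase TOP2A (3.27-fold), lower with DLX3 than with empty vector, were also among the 3 genes by which the empty-vector array stood highest above both others, with the adhesion gene MPZL2 (3.85-fold). DNA replication genes had a median of -0.07 (percentile 20.1, 28 genes) in this comparison; the ribonucleotide reductase genes RRM2 and RRM1 were 2.0-fold and 1.15-fold lower. Genes lowest on the empty-vector array against both others were NPIPA1, SERPINB3 and PPFIBP1, 3.05-fold, 3.04-fold and 2.94-fold higher with DLX3. In all 505 genes were 2-fold apart, 226 higher and 279 lower with DLX3, and signals correlated across genes at Pearson's r = 0.941 (genes are not independent replicates).

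Against untransduced cells alone, DNA replication genes were higher with DLX3: all 28 measured, 23 at least 2-fold, with a median of 1.69 (percentile 100). Mitosis genes had a median of 0.34 (percentile 93.0), with 7 genes at least 2-fold higher and 2 lower, and the median was 0.00 with spike-in scaling. RRM2 was 3.76-fold and RRM1 3.39-fold higher than in untransduced cells. TFRC, the transferrin receptor, was 19.2-fold higher, the simple epithelial keratin gene KRT7 10.4-fold and the epithelial adhesion gene EPCAM 7.69-fold. KRT4, a keratin of mucosal epithelia, was 11.7-fold lower, with NALF2 (6.56-fold) and the ubiquitin ligase gene RBCK1 (5.88-fold). The comparison held 1720 genes 2-fold apart, 929 higher and 791 lower, with r = 0.850 across genes.

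Empty-vector and untransduced cells, which differ without DLX3, were set against each other as the background. Replication genes were all higher on the empty-vector array, 25 of 28 at least 2-fold (median 1.79, percentile 100), and 31 of 32 mitosis genes were (21 at least 2-fold; median 1.482, percentile 100). TFRC was 26.9-fold, KRT7 12.4-fold and EPCAM 7.70-fold higher, and KRT4 13.4-fold, NALF2 8.03-fold and RBCK1 5.95-fold lower. Lower on the empty-vector array were the basal (-0.52, percentile 0.26), early (-0.72, 0) and late differentiation (-0.39, 0.22) lists, immediate early genes (-0.76, 0), unfolded protein response genes (-0.57, 0.03), TGF-beta and BMP targets (-0.62, 0.33) and p53 targets (-0.43, 1.42). Higher were cholesterol synthesis genes (0.66, percentile 99.8), cytokine genes (0.43, 98.8; -0.17 without the probe sets that carry the suffixes _x_at and _s_at), the Merkel and sweat gland markers (0.87, 99.5) and the leukocyte list (0.20, 98.2; -0.0088 without a floor). The others lay within the central 95% of random lists. Their medians, with percentiles in brackets, were heat shock 0.34 (93.8), EGF family -0.42 (3.96), interferon 0.36 (97.3), STAT3 -0.31 (4.50), and hypoxia 0.26 (92.4). They were WNT -0.15 (10.8), DLX3-linked -0.24 (4.18), hyperproliferation -0.13 (14.5), cell cycle inhibitors 0.05 (72.4), ribosomal -0.14 (22.4), housekeeping 0.12 (75.7) and fibroblast 0.00 (54.9). The fibroblast median was 0.37 with spike-in scaling, over the genes kept after it. In all 1113 genes were 2-fold apart, 659 higher and 454 lower on the empty-vector array, with r = 0.899. The control arrays thus differed in more genes than the 505 apart between DLX3-Flag and empty vector. With spike-in scaling these counts were closer, at 1208 and 1121. Over the 3 pairs, 31 of 75 list medians lay outside the central 95% of random lists. The pairs share arrays, so that they are not independent of each other.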

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

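The tests of explanations in this part, spike-in and bright-probe scaling and the floor for further probe sets were chosen only after the result was seen; median scaling and quantile normalization were planned. Control probe sets that no comparison uses stood out on the DLX3-Flag array: 5 ribosomal RNA probe sets were above the floor and at least 2-fold above both other arrays. The 28S ribosomal RNA 5′ probe set had a signal of 3087.1 (213.5 and 223.4 on the empty-vector and untransduced arrays) and the 28S middle probe set 3948.1 (800.2 and 526.2). The 18S ribosomal RNA probe sets had 952.8 at the 3′ end (107.6 and 33.8), 526.9 at the 5′ end (8.3 and 20) and 438.3 in the middle (87.3 and 80), all below the floor on the other arrays.

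These signals came from the array that gave the 139 higher and 186 lower genes, and whether they bear on those genes was not tested. Scaled by the hybridisation spike-ins, which were 1.45-fold and 1.34-fold higher on the DLX3-Flag array, 21 genes were higher than both controls. The count was 67 with median, 123 with quantile and 127 with bright-probe scaling. With the empty-vector array set apart the counts were, in the same order, 234, 57, 50 and 47. As deposited that array lay between the others, so its counts are no background rate. How far scaling may account for the higher genes therefore stays open. The heat shock list kept a median of at least 0.44 against empty vector under the 4 other scalings, which argues against scaling as its whole cause, and 3′ to 5′ ratios at most 1.19 times those of a control argue against 3′ bias. For the lower genes scaling stays open: they numbered at least 193 under those scalings (186 as deposited), but each of these lowered the median of all genes on the DLX3-Flag array against both controls, which favours a larger count, and quantile normalization kept 184 of the 186. Misreading probe sets stay open as well, since 84.2% of further probe sets had the direction of the higher genes but only 29 of 76 were also 2-fold apart, and only 54 of the 139 genes had one. Ribosomal RNA carried into the labelled sample, another difference in the array's preparation, and DLX3 itself stay open, because 1 array carries them all.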

How the results depend on the processing

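Spike-in scaling, scaling by bright probe sets, counts against each control alone, the EGF family list without feedback inhibitors and the floor for further probe sets were chosen after seeing the data; the others were planned. Of 121 counts of genes over all alternatives, 51 were within 1.5 times the main count and 70 were not. The values of those 70 follow, in the order DLX3-Flag higher and lower, empty vector higher and lower, untransduced higher and lower, then 2-fold apart for DLX3-Flag against empty vector, DLX3-Flag against untransduced and empty vector against untransduced, leaving out counts within 1.5 times. A floor at the 30th percentile gave 338, 296, 116, 126, untransduced lower 727, and 1163, 2598 and 1803; a floor at the 70th gave 67, 94, 31, 9, 206, 220, 245, 963 and 605; no floor gave 743, 727, 404, 761, 800, 1313, 2881, 4272 and 3655. A pseudocount gave 41, 107, 30, 13, 189, 300, 263 and, for empty vector against untransduced, 712. A threshold of 1.5-fold gave 600, 523, 252, 202, 900, 1083, 1831, 3358 and 2764, and of 3-fold 19, 36, 9, 2, 58, 145, 95, 574 and 300. Without _x_at and _s_at probe sets the counts were 84, 107, 33, untransduced 180 and 281, and 314, 1016 and 659. Spike-in scaling gave 21, 603, 234, 9 and, for DLX3-Flag against empty vector, 1121; median scaling gave 67 DLX3-Flag higher, and the mean over probe sets 20 empty vector lower. Against the empty vector alone 226 were higher, and against untransduced cells alone 929 higher and 791 lower. Floors, thresholds and fewer probe sets change how many genes can pass by construction. A count against 1 control alone cannot be below the count against both, and a pseudocount shrinks each fold from its value without a floor. Median and spike-in scaling lowered the DLX3-Flag array against both controls, which favours fewer higher and more lower genes on it. Spike-in scaling also raised the empty-vector array against both others. For the mean over probe sets the cause was not tested. Over the alternatives 636 list values stayed within 1 SD of the random lists' medians from the main value, 265 moved by more and 2 reversed. For named genes 2826 stayed within the spread of all genes between the control arrays, 214 moved by more and 8 reversed. That spread was 0.62 on the log2 scale, wider than any shift by median, spike-in or bright-probe scaling. With spike-in scaling the median of all genes moved by -0.44 for DLX3-Flag minus empty vector. A gene clear of the floor moved further, SQSTM1 from 2.03 to 1.49, but still by less than the spread. Median, spike-in and bright-probe scaling could therefore move a named gene by more than the spread only through the floor, and the gene count says little about scaling. Only list medians outside the central 95% of random lists and genes at least 2-fold apart were counted as reversed; among the others 64 list values and 49 gene values changed sign. Reversed values were the cytokine list, empty vector minus untransduced, at -0.17 without _x_at and _s_at probe sets, and the leukocyte list at -0.0088 without a floor. B4GALT1 was at -0.67 and -1.52 against empty vector and untransduced with the middle probe set and at -0.37 against untransduced with the mean; RBL2 was at -0.056 against empty vector with the middle probe set. NRG1 was at 0.19 and 0.19 and EGFR at 0.52 and 0.52 without _x_at and _s_at probe sets, where another probe set stands for the gene. Of the 31 list medians outside the central 95% of random lists, 29 stayed outside with median, 30 with quantile, 31 with spike-in and 31 with bright-probe scaling. Median, spike-in and bright-probe scaling multiply each array by 1 factor. Apart from the floor, this shifts a list and its random lists alike, so these counts could hardly change and do not test scaling. Without matching 32 were outside and 3 crossed a limit. Without a floor 34 of 76 further probe sets of the higher genes and 49 of 101 of the lower genes were 2-fold apart, and 64 and 89 had their direction. Signals under the floor of 162.8 limit what can be said of dim genes. No paired analysis was possible because each group has 1 array.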

Other observations

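The tests of explanations in this part, its NRF2, metallothionein, connexin, lysosome and ERK output lists and the genes named from those lists were chosen only after results had been seen, while the immediate early, mitosis and DNA replication lists were fixed beforehand. Metallothioneins, small proteins that bind zinc and copper, were lower on the DLX3-Flag array: 5 of 6 measured genes were at least 2-fold lower than both controls, with a list median of -1.88 against empty vector (percentile 0) and -1.34 against untransduced cells (percentile 0.04). MT2A had a signal of 6313 with DLX3, 24769 with empty vector and 16385 without transduction, and MT1X 3289, 12927 and 8147. Further probe sets of MT1X (-1.15 and -0.64) and MT1F (-0.33 and -0.61) were under 2-fold from a control. These and the further probe set of MT1E carry the suffix _x_at. The list was not described without such probe sets, so whether its genes are separate readings was not tested. MT1H was 2.88-fold lower than with empty vector but near untransduced cells (3468 and 3095). Of 3 measured gap junction connexins, GJA1 was 2.94-fold and 3.20-fold lower and GJB5 2.88-fold and 5.82-fold lower (list medians -1.53 and -1.68, percentiles 0.01 and 0.23). All metallothioneins and both of these connexins had been seen before the lists were written, so the percentiles are no independent evidence.

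Targets of NRF2, the regulator of the oxidative stress response, had 4 of 23 measured genes higher than both controls: SQSTM1, GCLM (2.69-fold and 5.14-fold), TXNRD1 (2.54-fold and 4.69-fold) and OSGIN1 (at least 3.04-fold from either). With spike-in scaling GCLM (log2 difference 0.89) and TXNRD1 (0.80) were under 2-fold from empty vector, and 2 of the 4 remained. The list, with medians of 0.21 and 0.41, lay at the 98.2nd and 97.8th percentiles, but the 20 genes not seen before lay at the 81.0th and 76.7th, within the range of random lists. Lysosomal genes, of which SQSTM1, shared with the NRF2 list, NEU1 (2.29-fold and 3.02-fold), SLC17A5 (2.46-fold and 3.30-fold) and IDS (2.34-fold and 3.33-fold) were the 4 of 25 measured higher than both controls, lay at the 99.8th and 96.7th percentiles (medians 0.38 and 0.47), and the 21 not seen before at the 85.2nd and 21.4th. With spike-in scaling NEU1 (0.66), SLC17A5 (0.76) and IDS (0.69) were under 2-fold from empty vector, and none of 4 further IDS probe sets was 2-fold above both controls. The list does not hold the lysosomal protease gene CTSC, which was 4.74-fold and 5.71-fold lower.

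EGFR, EREG, NRG1, DUSP6, FOS, EGR1 and MYC were lower on the DLX3-Flag array than on both controls, though 1 dim further probe set each of EGFR and NRG1 was higher. Of the other further probe sets, 3 of EGFR were lower than both controls, and 2 of NRG1 were lower than in untransduced cells and at the floor with empty vector. JUN, of the same immediate early list as FOS, EGR1 and MYC, went the other way. It was 2.06-fold and 2.48-fold higher, though under 2-fold from a control with median and spike-in scaling. A hypothesis is that ERK pathway output may be lower, which the ERK output set left undecided. Its 9 measured genes had medians of -0.29 and -0.71 (percentiles 7.08 and 1.69). The 7 not marked as seen before lay at the 19.3rd percentile against empty vector and the 3.69th against untransduced cells. Of these 7, SPRY2 and SPRY4 had already counted in the median of the EGF family list, so the 7 are no independent check. DUSP4 (2.05-fold and 1.64-fold lower) and SPRY2 (2.11-fold and 1.87-fold lower) were below both controls, while CCND1 (680, 627 and 582) was not. A general loss of short-lived transcripts was left undecided too, since the immediate early list had a median of -0.12 against empty vector (percentile 20.4) and -1.35 against untransduced cells (percentile 0).

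DNA replication genes were higher on both retroviral arrays than on the untransduced one. The lowest median of empty vector minus untransduced was 1.76 over the other scalings. Those scalings moved the median of all genes of this pair by only -0.04 to 0.09, so this could hardly come out otherwise and does not test scaling. A factor common to an array shifts random lists alike, apart from the floor. The replication list lay at percentile 100 against untransduced cells with empty vector (median 1.79) and DLX3 (1.69), which argues against such a factor as its whole cause. More cycling cells in the transduced cultures is a candidate explanation for the empty-vector array, where mitosis genes were higher too (median 1.482), but with DLX3 the mitosis list lay at the 93.0th percentile, which decides nothing. Whether transduction or the culture set the difference cannot be told apart, because there was 1 untransduced array.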
